A study of Mus musculus with 6 samples.

How the data were processed

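Total RNA sequencing was read from 6 libraries of mouse splenic B cells, 3 infected with the empty retroviral vector pMIR and 3 with pMIR-Sox2. Per the labels' protocols, B cells of C57Bl/6 mice aged 4 months were cultured with anti-CD40 at 1 µg/ml and IL-4 at 12.5 µg/ml, infected after 24 and 48 h, and sorted after 96 h for the mCherry carried by the vector. The groups and replicate numbers come from the sample titles. The sample descriptions carry a shared number, 8, 9 or 12, for the members of each replicate pair.

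The deposited table holds raw counts per Ensembl gene, 1 column per library, with 37620 genes. Per the submitters' processing notes, Trimmomatic 0.32, TopHat2 2.0.11, Bowtie2 2.2.2, SAMtools 0.1.19, HTSeq 0.6.1p1 and the mouse build mm9 were used, with no role or order given. The strand setting of the counting and the annotation release were not given in the sources used here. The 5 closing lines of the table (alignment not unique, ambiguous, no feature, not aligned, too low quality) name no gene, and they stayed out of library sizes and tests. Alignments that were not unique made up 25.7 to 26.0% of a library's total in pMIR and 23.1 to 26.5% in pMIR-Sox2. Reads in no feature made up 11.4 to 13.1% and 12.1 to 14.6%, with Wilson 95% intervals of at most 0.0114 points to either side. Reads not aligned made up 8.55 to 9.65% and 8.51 to 8.92%, and ambiguous reads 0.283 to 0.307% and 0.284 to 0.289%. The low quality line was 0 in each library. Intervals and count limits cover counting error only.

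Gene counts per library were 27692437, 21672921 and 21421769 in pMIR replicates 1 to 3 and 20770447, 18052422 and 17153805 in pMIR-Sox2 replicates 1 to 3. CPM below are gene counts scaled to the library's effective size, which is its gene counts after the filter times its TMM factor. The filter and the TMM scaling are those of the gene test below. TMM factors ran from 0.969 to 0.980 in pMIR and from 1.01 to 1.05 in pMIR-Sox2. CPM are a relative measure that says nothing of RNA per cell. The reference used here, GENCODE M21 on GRCm38, is another build than mm9. It served for gene class, overlap and names, and no coordinates were used. It held 32897 of the 37620 identifiers, and 26952 of these had the symbol given in the table. Symbols are those of the deposited table.

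Genes were tested with edgeR 4.0.16 in R 4.3.3 after filterByExpr with the group, TMM scaling, and robust quasi-likelihood fits of pMIR-Sox2 against pMIR, with Benjamini-Hochberg adjustment over the 12899 genes tested and a threshold of 0.05. An adjusted p without another name is from this test. Sox2, the introduced gene, was left out of counts of genes and lists. Standard errors (SE) are those of the log2 fold change, computed as its size over the square root of F, and errors of CPM are SD over n = 3 libraries. The common biological coefficient of variation was 14.4%. The test was run on simulated data of the same comparison with 12416 genes, 50 of them changed at each fold. It recovered 14 at 1.5-fold, 42 at 2-fold, 45 at 4-fold and 47 at 8-fold, with 13 false calls. The labels do not say whether the replicates were separate animals, so p-values measure the spread between these samples.

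The 32 gene lists were written from textbook knowledge before the data were examined, as were the tests of the comparison and the rule for named genes. Most tests of explanations in the closing part were chosen later, as stated there. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. An estimated correlation and fry, which tests whether a list's genes move on balance one way, were run beside it. None of the 13 calls made with the preset held with the estimated correlation, and 7 of them held by fry. The adjusted p of 0.757 with the estimated correlation is 1 value that the adjustment gave to all 13. Their unadjusted camera p with it ran from 0.0737 for IL-4 and STAT6 to 0.606 for cytoplasmic ribosomal proteins. A simulated list was found by camera with either correlation and by fry, and no other of the 28 lists tested was called. The simulated genes were drawn independently of each other, whereas the correlation estimated in these data reached 0.96 for cytoplasmic ribosomal proteins. The simulation thus does not show how the list tests behave with correlated genes. Counts of members that rose or fell are over all genes tested, and counts adjusted over the list alone stand beside them. The rule named Sox2, Ighm, Ighg1 and Ighe, then the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap of libraries, leaving out Sox2, predicted genes, pseudogenes and immunoglobulin segments. It also named up to 4 members with the smallest adjusted p from each list, or 2 of highest CPM given as values only. Members named in the report outside this rule, to illustrate the changes, were chosen after their values were seen. These are Ighg2c, Sox14, Sox13, Pax6, Nes, Msi1, Egfr, Pax5, Prdm1, Ms4a1, Cd38, Cd40, Mx1, Ndufa4 and Jun. Some genes taken by the rule and 1 of the lists are not reported here.

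A fold against pMIR libraries that were all at 0 was computed against a floor of 3 counts over the group and is written as a lower bound. With 1 to 3 pMIR counts, the ratio is given with its exact 95% counting interval. Alternatives were DESeq2 1.42.0 size factors, library totals only, no filter and a stricter filter on low counts, the DESeq2 Wald test, limma-voom, a fold minimum of 1.5, leaving out immunoglobulin genes, the replicate number as a block, and each library left out in turn. Library totals only was added for the gene lists after seeing the data. Deviations from the group mean correlated across genes between the pMIR and pMIR-Sox2 libraries of the same number by 0.242, 0.359 and 0.189, all above 0.1, against 0.0341 at most for libraries of different numbers. On this ground, and by the replicate number of the titles and the shared number of the descriptions, the numbers pair the samples. The main test does not use this pairing. The block is given where it changes the call of a list or of a gene taken by the rule. Its counts of list members are given for some lists only, and more members often passed with it. With it 7 rose and 12 fell in class switching, and 3 and 25 in CD40 and NF-kB. In the unfolded protein response 3 rose and 22 fell, and among p53 targets 6 and 13. Of 127 genes taken by the rule, 39 share exon bases with another gene in M21, 30 of them with a gene on the other strand, and reads of such partners cannot be told apart without the strand setting. Close paralogs such as immunoglobulin, Bcl2a1, histone, Hbb and Eno1 genes share sequence, and reads that align to several places were not counted in them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.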

Results

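The series measured total RNA of activated mouse B cells carrying either an empty retroviral vector, pMIR (3 libraries), or the same vector with Sox2 (pMIR-Sox2, 3 libraries). Anti-CD40 and IL-4 drive B cells to proliferate and to switch their antibody class towards IgG1 and IgE. The title of the series concerns Sox2 in class-switched B cells. Gene counts ran from 21421769 to 27692437 per library in pMIR and from 17153805 to 20770447 in pMIR-Sox2. Genes took 51.9 to 53.2% of the table's total in pMIR and 52.3 to 53% in pMIR-Sox2. The first principal component held 83.5% of the variance. On it the pMIR libraries lay at −54.9, −54.2 and −52.1, and the pMIR-Sox2 libraries at 57.9, 68.3 and 35.0, with pMIR-Sox2 replicate 3 nearest to pMIR.

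The comparison of pMIR-Sox2 with pMIR asks which transcripts change when a B cell in switching culture is given Sox2. Sox2 itself (ENSMUSG00000074637) was read at 0.949 ± 0.744 CPM (SD, n = 3) in pMIR and at 800 ± 183 CPM (n = 3) in pMIR-Sox2. All 6 tested heavy chain constant genes fell, Ighg1 from 841 ± 91.7 to 152 ± 34.0 CPM (n = 3 each). Most tested genes of ribosome biogenesis, cholesterol synthesis, the unfolded protein response and the CD40 response fell. Genes that pMIR cells hardly express, among them Sox21, Sox3 and Vipr2, rose, and so did Sox4 and Tcf12, an E protein transcription factor (110 ± 1.05 to 820 ± 201 CPM). In all, 2990 genes rose and 2577 fell, 43.2% of those tested. The balance depends on scaling, as 53.7% of these genes rose, against 62.4% with library totals only (3414 rose and 2059 fell). Of the 2990 genes that rose in the main test, 1375 did so by over 2-fold and 278 by over 8-fold. Of the 2577 that fell, 658 did so by over 2-fold and 25 by over 8-fold. The libraries of the groups did not overlap in 56.5% of genes tested, against 10% given by chance for 3 against 3.

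For Sox2 the log2 fold change was 9.73 ± 0.42 (SE, adjusted p = 4.74e-06), and it was 10.47 without pMIR replicate 3. The pMIR libraries held 20, 7 and 37 Sox2 counts, and the pMIR-Sox2 libraries 21528, 14536 and 10763. Reads of the introduced coding sequence and of the endogenous gene cannot be told apart, and the source of the pMIR counts was not tested. The neighbouring transcript Sox2ot had 1 count over the pMIR libraries and 56 over the pMIR-Sox2 libraries. A two-sided exact permutation test gave 0.1 for Sox2, the smallest p that 3 libraries against 3 allow.

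**Figure D1:**
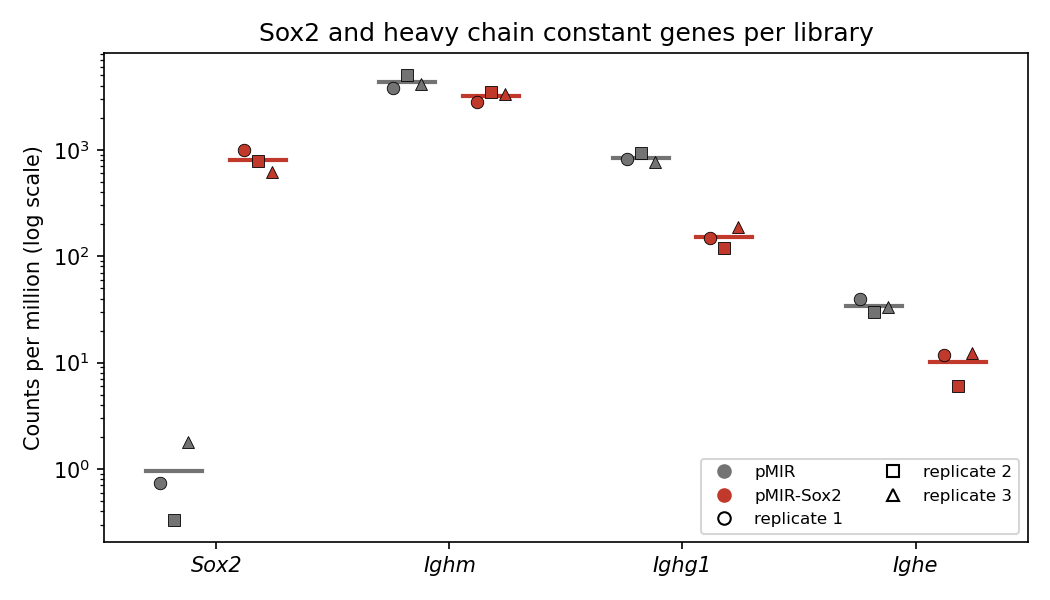
CPM on a log scale of Sox2, Ighm, Ighg1 and Ighe in each library, with pMIR in grey, pMIR-Sox2 in red, symbols for replicates and a line at each group's mean. Group means of Ighg1 were 841 CPM in pMIR and 152 CPM in pMIR-Sox2, and those of Ighe 34.3 and 10.1 CPM.

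Heavy chain constant genes, whose transcripts show which antibody class a cell expresses or prepares to switch to, fell in 6 of 6 tested members (6 when adjusted over the list alone). Ighg1 fell from 841 ± 91.7 to 152 ± 34.0 CPM (−2.47 ± 0.17, adjusted p = 2.36e-05). Ighe fell from 34.3 ± 5.19 to 10.1 ± 3.56 CPM (−1.76 ± 0.25, adjusted p = 0.000686). Ighg3 (−3.68), Ighg2b (−3.24) and Ighg2c (−4.26) fell further. Ighm, the constant region of unswitched IgM, fell least, from 4331 ± 631 to 3211 ± 353 CPM (−0.43 ± 0.15, adjusted p = 0.0394). For Ighm the adjusted p was 0.154 without pMIR replicate 2, 0.0925 without pMIR replicate 3, 0.0841 without pMIR-Sox2 replicate 1, 0.0542 without pMIR-Sox2 replicate 3 and 0.0596 with library totals only. The counts do not separate germline from switched or membrane from secreted transcripts. As a list the genes were lower, with camera adjusted p = 0.000591 at the preset correlation and adjusted p = 0.757 with an estimated correlation.

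The 10 largest rises were of genes near or at 0 in pMIR. Vipr2, a receptor for vasoactive intestinal peptide, reached 20.3 ± 6.99 CPM from 0 counts, at least 467-fold higher. Col6a4 (9.36 ± 3.05 CPM, at least 215-fold) and Lix1 (9.23 ± 4.62 CPM, at least 212-fold) had no pMIR count either. Sox21 had 2 pMIR counts and reached 18.6 ± 5.64 CPM, a ratio of 656 (interval 181 to 5420). Tshb, the beta subunit of thyrotropin, had 1 pMIR count and a ratio of 476 (84.9 to 18841). Mobp, a myelin protein gene, had 3 and a ratio of 306 (104 to 1489). Kctd12b rose from 0.267 to 83.7 ± 33.8 CPM (log2 fold change 8.22), Pcp4 from 0.322 to 91.6 ± 46.6 CPM (8.14), Apod from 0.153 to 42.0 ± 22.6 CPM (8.12), and Slc18a2, the vesicular monoamine transporter, from 0.165 to 39.9 ± 20.2 CPM (7.91). Without pMIR replicate 3 the values were 8.75 for Pcp4, 9.26 for Apod and 8.80 for Slc18a2. Without pMIR replicate 1, Sox21 and Tshb had no pMIR count, so no fold is given for them there, and the fitted log2 fold change of Mobp became 8.78.

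The largest falls included genes of the immune response. Beside Ighg3, Batf3, a transcription factor, fell from 6.55 ± 2.29 to 0.269 CPM (−4.62 ± 0.41). Il1r2, the decoy receptor for IL-1, fell from 32.8 to 2.23 CPM (−3.90), and Il2rb, the beta chain of the IL-2 receptor, from 6.89 to 0.523 CPM (−3.68). Parm1 (−3.86), H2-M5 (−3.57) and Mylk (−3.52) also fell. Igj, the joining chain of secreted IgM and IgA, fell from 24.5 ± 21.1 to 1.19 CPM (−4.36), and Lifr from 24.2 ± 18.3 to 2.32 CPM (−3.39). Both were high in pMIR replicate 2, and without it the values were −3.38 for Igj and −2.57 for Lifr.

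Among the machinery of class switching and somatic hypermutation, 5 of 40 tested members rose, 9 fell and 26 did not pass (4 and 8 adjusted over the list alone; camera adjusted p = 0.343). Ung, the uracil glycosylase of base excision repair, fell from 67.0 ± 6.88 to 39.2 ± 8.04 CPM (−0.77). Polh, a translesion polymerase, rose from 33.9 ± 2.15 to 66.9 ± 8.13 CPM (0.98), and Lig4, the ligase of end joining, from 6.45 ± 1.21 to 15.1 ± 0.939 CPM (1.23). The list's falls numbered 4 without pMIR replicate 1, and its rises 3 without pMIR-Sox2 replicate 1.

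Genes of mature B cell identity fell in 20 of 36 tested members, rose in 7 and did not pass in 9 (20 and 10 adjusted over the list alone). Cxcr5, the follicle homing receptor, fell from 210 ± 17.0 to 79.0 ± 7.39 CPM (−1.41), and Tnfrsf13c, the BAFF receptor, from 284 ± 16.2 to 86.4 ± 20.7 CPM (−1.72). Ms4a1, which encodes CD20, also fell (−1.79). Cr2, a complement receptor, rose from 8.07 ± 0.877 to 55.8 ± 20.8 CPM (2.79), Cd72 from 93.3 ± 19.4 to 259 ± 42.8 CPM (1.47), and Cd38 by 2.79. The transcription factors Ebf1, from 123 ± 14.8 to 229 ± 36.6 CPM (0.89), and Pax5 (0.89) rose too. As a list these genes were lower at camera adjusted p = 0.0423, with adjusted p = 0.757 with an estimated correlation and 0.0541 by fry. This call ended without pMIR replicate 2 (0.113), without pMIR-Sox2 replicate 1 (0.0735) and with the replicate block (0.0632, with 11 rises). Of 21 germinal centre genes, 6 rose, 7 fell and 8 did not pass (6 and 10 adjusted over the list alone; camera adjusted p = 0.278); 12 fell with the replicate block. Pou2af1 (−0.88) and Basp1 (−1.62) fell, and Rgs13 rose from 0.225 to 1.02 CPM (2.19). Of 27 plasma cell genes, 8 rose, 11 fell and 8 did not pass (8 and 11 adjusted over the list alone; camera adjusted p = 0.179). Derl3 (−1.98), Ell2 (−0.95) and Slamf7 (−1.20) fell, and Trp53inp1 rose from 127 ± 13.2 to 404 ± 110 CPM (1.67) and Prdm1, the plasma cell regulator, by 1.19.

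Most tested genes of the responses to CD40 and IL-4, the stimuli of the culture, fell. Of 34 CD40 and NF-kB genes, 22 fell, 3 rose and 9 did not pass (23 and 4 adjusted over the list alone), with camera adjusted p = 0.000174 and adjusted p = 0.757 with an estimated correlation. Bcl3 fell from 74.5 ± 14 to 28.4 ± 3.28 CPM (−1.39), Map3k14, the kinase NIK, from 52.9 ± 2.31 to 24.1 ± 3.74 CPM (−1.13), and Irf4 from 472 ± 166 to 143 ± 17.1 CPM (−1.72), and Cd40 itself also fell (−1.44). Ebi3 rose from 61.1 ± 9.67 to 123 ± 12 CPM (1.00). The rises numbered 1 without pMIR replicate 1, without pMIR-Sox2 replicate 1 and without pMIR-Sox2 replicate 2. Of 27 IL-4 and STAT6 genes, 16 fell, 3 rose and 8 did not pass (16 and 3 adjusted over the list alone), with camera adjusted p = 0.0106 and adjusted p = 0.757 with an estimated correlation. Zbtb32 fell from 8.08 ± 1.28 to 0.929 ± 0.565 CPM (−3.13), Pim1 from 512 ± 49.4 to 251 ± 23.7 CPM (−1.03) and Batf from 136 ± 13.7 to 63.6 ± 5.80 CPM (−1.09), while Gfi1 rose from 15.2 ± 2.09 to 57.1 ± 6.41 CPM (1.91). Of 25 immediate early and dissociation stress genes, 11 fell, 1 (Jun, 0.68) rose and 13 did not pass (12 and 1 adjusted over the list alone), with camera adjusted p = 0.00119, adjusted p = 0.757 with an estimated correlation and 0.0541 by fry. Jun did not pass without pMIR replicate 1 or without pMIR replicate 2. Egr2 fell from 644 ± 25.8 to 187 ± 74.2 CPM (−1.78), Junb from 672 ± 70.1 to 240 ± 29.6 CPM (−1.48), and Dusp2 (−1.66) and Nr4a1 (−1.82) also fell.

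Most tested genes of ribosome biogenesis, sterol synthesis and protein folding fell. Of 34 MYC and ribosome biogenesis targets, 31 fell, 0 rose and 3 did not pass (32 and 0 adjusted over the list alone), with camera adjusted p = 3.97e-08, adjusted p = 0.757 with an estimated correlation and 0.0541 by fry. Ppan fell from 96.6 ± 14.7 to 37.8 ± 7.62 CPM (−1.35), Odc1, the first enzyme of polyamine synthesis, from 318 ± 34.8 to 147 ± 24.9 CPM (−1.11), and Polr1b (−1.30) and Wdr12 (−0.90) also fell. Of 23 cholesterol synthesis genes, 18 fell, 0 rose and 5 did not pass (19 and 0 adjusted over the list alone), with camera adjusted p = 5.32e-06 and adjusted p = 0.757 with an estimated correlation. Cyp51, lanosterol demethylase, fell from 373 ± 32.8 to 188 ± 39.3 CPM (−0.99), and Mvd (−1.09) and Sqle, squalene epoxidase (−0.88), also fell. In both lists 0 genes were higher in edgeR at an unadjusted p under 0.05, and 0 rose by the DESeq2 Wald test or limma-voom. Of 29 genes of the unfolded protein response, 19 fell, 2 rose and 8 did not pass (20 and 3 adjusted over the list alone), with camera adjusted p = 0.000125 and adjusted p = 0.757 with an estimated correlation. Sdf2l1 fell from 151 ± 2.00 to 70.3 ± 12.6 CPM (−1.10), Syvn1 (−0.94) and Creld2 (−0.81) fell too, and Atf6 rose from 215 ± 3.26 to 344 ± 25.1 CPM (0.67). The list's rises numbered 1 without pMIR replicate 3. Glycolysis and hypoxia genes went both ways, with 6 of 34 rising, 7 falling and 21 not passing (6 and 7 adjusted over the list alone; camera adjusted p = 0.815; median −0.09, mean 0.00). Pdk1 rose from 210 ± 13.0 to 632 ± 86.3 CPM (1.59), Ndrg1 by 1.72 and Eno1 by 0.86. The falls numbered 3 without pMIR replicate 3, 4 without pMIR-Sox2 replicate 1 and 3 without pMIR-Sox2 replicate 2.

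Most tested genes of the Sox family and of neural progenitors rose. Of 6 other Sox genes tested, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with camera adjusted p = 0.00661 and adjusted p = 0.757 with an estimated correlation. Their median log2 fold change was 5.36, and 4.76 with the 1 gene at 0 in pMIR placed at its bound. Sox4, active in early lymphocytes, rose from 39.9 ± 8.80 to 956 ± 143 CPM (4.58 ± 0.20, adjusted p = 4.39e-06). Sox3, the closest relative tested, rose from 0.246 to 17.8 ± 5.04 CPM (6.14), Sox14 from 0 counts to 1.33 CPM and Sox13 by 0.96, while Sox12 fell from 20.8 ± 1.14 to 7.10 ± 1.65 CPM (−1.55). Sox21 is in this list and in that of neural progenitor genes, where 7 of 13 rose, 3 fell and 3 did not pass (7 and 3 adjusted over the list alone), with camera adjusted p = 0.0309 and adjusted p = 0.757 with an estimated correlation. Dll1, a Notch ligand, rose from 2.45 ± 0.430 to 22.0 ± 7.19 CPM (3.16), Zic2 from 0.0882 to 2.56 CPM (4.79), and Pax6 by 2.30. Sox21 had no pMIR count without pMIR replicate 1, so no fold is given for it there. Nes (−1.45), Msi1 (−1.84) and Egfr (−1.42) fell. The neural list's call ended without pMIR replicate 2 (0.0604), with the replicate block (0.0632) and with library totals only (0.0537).

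Pluripotency genes were mostly not expressed, and of 7 tested 2 rose, 2 fell and 3 did not pass (2 and 2 adjusted over the list alone; camera adjusted p = 0.651). Spp1 rose from 4.38 ± 1.62 to 30.7 ± 13.9 CPM (2.81), and Klf2 fell from 261 ± 56.4 to 81.8 ± 57.4 CPM (−1.68, adjusted p = 0.0113). Klf2 had adjusted p = 0.0749 without pMIR-Sox2 replicate 2 and 0.133 with no filter, and a log2 fold change of −2.40 without pMIR-Sox2 replicate 3. Tfcp2l1 (1.51) lost its call without pMIR replicate 1 (0.0525) and pMIR-Sox2 replicate 1 (0.066). Dnmt3l (−1.35) lost its call without pMIR replicates 1 (0.0575) and 3 (0.0828) and pMIR-Sox2 replicates 1 (0.0628) and 2 (0.0743). Of 12 WNT target genes, 5 rose, 4 fell and 3 did not pass (5 and 5 adjusted over the list alone; camera adjusted p = 0.815; median −0.28, mean 0.49). Tnfrsf19 rose from 1.34 ± 0.806 to 104 ± 19 CPM (6.28), Tcf7 fell (−2.44), and Myc fell from 414 ± 87.2 to 209 ± 33.9 CPM (−0.98). The WNT rises numbered 3 without pMIR replicate 1 and 3 without pMIR replicate 2.

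**Figure D2:**
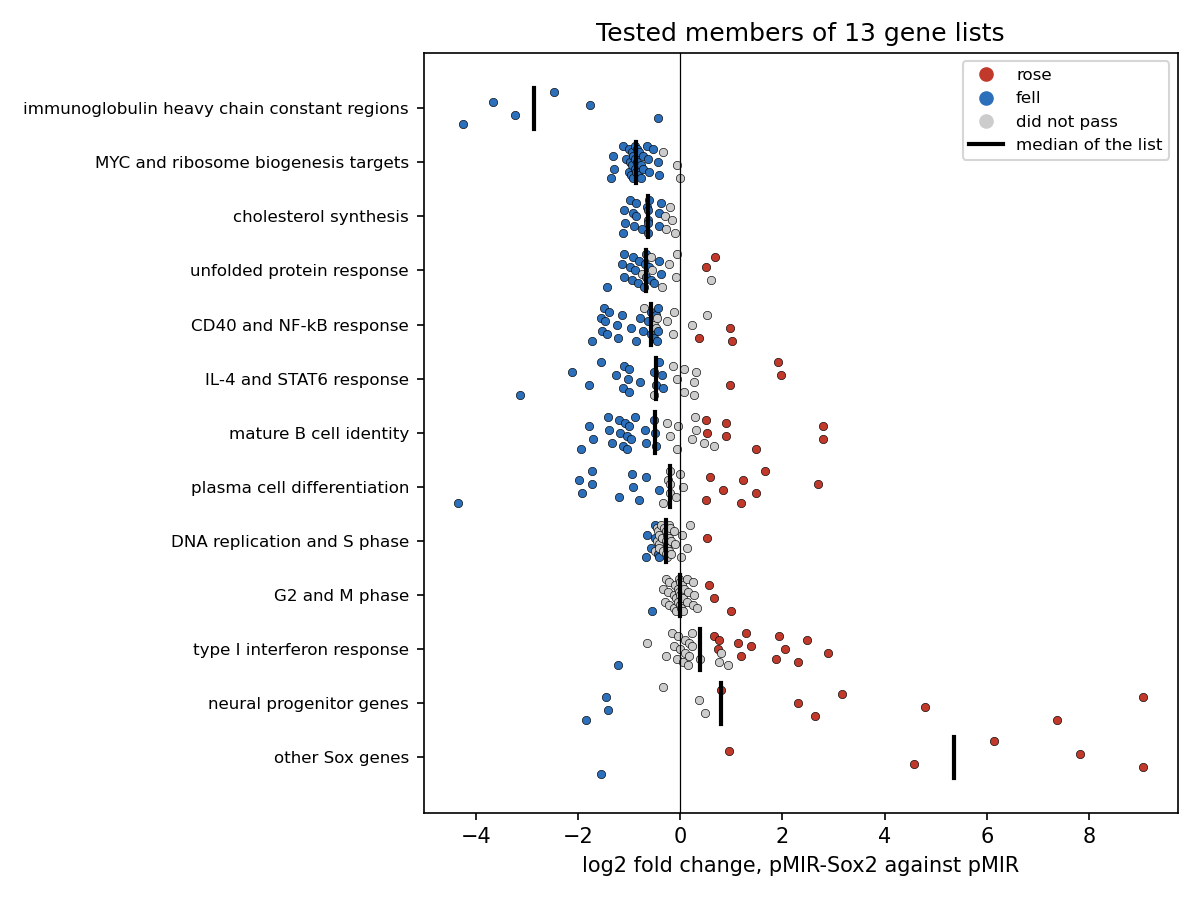
Log2 fold change of pMIR-Sox2 against pMIR for each tested member of 13 gene lists, with members that rose in red, that fell in blue and that did not pass in grey, and a black line at the list's median. The medians ran from −2.86 for heavy chain constant regions to 5.36 for other Sox genes, whose median is 4.76 with the gene at 0 in pMIR placed at its bound.

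Type I interferon genes rose in 13 of 33 tested members, fell in 1 (Mx1, −1.22) and did not pass in 19 (13 and 2 adjusted over the list alone; 2 fell with the replicate block). Usp18 rose from 7.61 ± 2.37 to 42.0 ± 9.41 CPM (2.47), Rtp4 from 7.19 ± 1.17 to 35.5 ± 12.9 CPM (2.31), Cmpk2 by 2.04 and Dhx58 by 1.19. As a list they were higher at camera adjusted p = 0.0106, with adjusted p = 0.757 with an estimated correlation, 0.122 by fry and 0.0517 without pMIR replicate 1. Regulators of apoptosis of the BCL2 family fell in 6 of 14, rose in 3 and did not pass in 5 (7 and 3 adjusted over the list alone; camera adjusted p = 0.179, fry 0.0163). The survival genes Bcl2 and Mcl1 fell from 87.2 ± 0.969 to 37.8 ± 3.15 CPM (−1.20) and from 603 ± 25.7 to 346 ± 32.0 CPM (−0.80). Of the death-promoting genes, Bcl2l11, which encodes BIM, fell (−0.98), and Bmf rose from 6.50 ± 0.239 to 40.2 ± 15.6 CPM (2.63). Targets of p53 fell in 10 of 29, rose in 6 and did not pass in 13 (11 and 6 adjusted over the list alone; camera adjusted p = 0.247). Rrm2b rose from 17.5 ± 3.13 to 147 ± 25.6 CPM (3.07), and Sesn2 (−1.45) and Plk3 (−1.01) fell. The p53 falls numbered 5 without pMIR replicate 1 and 6 without pMIR-Sox2 replicate 2.

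Genes of DNA replication and S phase fell in 7 of 38 tested members, rose in 1 and did not pass in 30 (0 fell and 1 rose adjusted over the list alone, with 16 lower in edgeR at an unadjusted p under 0.05). As a list they were lower at camera adjusted p = 0.0045, with adjusted p = 0.757 with an estimated correlation and 0.264 by fry. Pola1 rose from 82.4 ± 7.80 to 118 ± 8.81 CPM (0.52), and Rfc2 fell from 145 ± 7.10 to 103 ± 17.0 CPM (−0.50). The number that fell was 1 without pMIR replicate 1, 2 without pMIR replicate 3, 2 without pMIR-Sox2 replicate 1, 2 without pMIR-Sox2 replicate 2, 23 without pMIR-Sox2 replicate 3, 4 with library totals only, 11 by limma-voom or the DESeq2 Wald test and 24 with the replicate block. Of 34 genes of G2 and M phase, 3 rose, 1 fell and 30 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.956; median −0.01, mean 0.03). Nusap1 rose from 147 ± 12.3 to 293 ± 20.2 CPM (1.00), Cenpf by 0.65 and Cenpe by 0.56, and Kif20a fell (−0.55), with adjusted p = 0.0558 without pMIR replicate 1. Rises numbered 7 without pMIR-Sox2 replicate 2, 6 with library totals only and 5 by the DESeq2 Wald test, falls 0 without pMIR replicate 1 and 5 without pMIR-Sox2 replicate 3, and the replicate block gave 7 rises and 5 falls.

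Few ribosomal, mitochondrial and histone genes passed the test. None of 43 cytoplasmic ribosomal protein genes passed in edgeR (0 adjusted over the list alone, 0 by the DESeq2 Wald test or limma-voom, 1 lower at an unadjusted p under 0.05, 1 fell with the replicate block), and their median was −0.18. The list was lower at camera adjusted p = 0.00857, with adjusted p = 0.757 with an estimated correlation, 0.339 by fry, 0.0518 without pMIR replicate 2 and 0.322 without pMIR-Sox2 replicate 1. Rpl4 had 3899 ± 146 CPM in pMIR and 3365 ± 429 CPM in pMIR-Sox2, and Rplp0 3401 ± 89.5 and 2926 ± 372 CPM. Of 33 oxidative phosphorylation genes, 4 fell (Uqcrq, Cycs, Ndufa5 and Atp5g1, −0.38 to −0.46), 1 rose (Ndufa4, 0.33) and 28 did not pass (0 and 0 adjusted over the list alone; 7 lower and 1 higher in edgeR at an unadjusted p under 0.05; camera adjusted p = 0.179). Falls numbered 0 without pMIR replicate 1, 2 without pMIR replicate 3, 2 without pMIR-Sox2 replicate 1, 1 without pMIR-Sox2 replicate 2 and 2 with library totals only. Rises numbered 0 without any of pMIR replicates 1, 2 and 3 and pMIR-Sox2 replicate 2, and 2 with library totals only. Of 20 histone genes 2 rose, 0 fell and 18 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.262, and 0.0362 without pMIR-Sox2 replicate 1). Hist1h1c rose from 32.1 ± 2.62 to 73.2 ± 18.6 CPM (1.19), and Hist1h3c rose by 0.61. Rises in this list numbered 1 without pMIR replicate 1 or 2 and without pMIR-Sox2 replicate 2 or 3. Hist1h3c had an adjusted p of 0.114 and 0.096 without pMIR replicates 1 and 2, and of 0.0584, 0.0526 and 0.0806 without pMIR-Sox2 replicates 1, 2 and 3. Of 10 mitochondrially encoded transcripts 1 fell, mt-Rnr2 (−0.49), 0 rose and 9 did not pass (0 adjusted over the list alone; camera adjusted p = 0.205, and 0.0192 without pMIR replicate 1). For the histone list 0 fell, and for the mitochondrial list 0 rose, also at an unadjusted p under 0.05 and by the DESeq2 Wald test or limma-voom. Mitochondrial falls numbered 3 without pMIR replicate 1 or pMIR-Sox2 replicate 3, 0 without any other library, 0 with library totals only or the stricter filter, 2 by the DESeq2 Wald test and 4 with the replicate block.

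Markers of other cell types were mostly not expressed, and those read went both ways. T cell markers rose in 3 of 12, fell in 2 and did not pass in 7 (4 and 2 adjusted over the list alone; camera adjusted p = 0.886; median −0.14, mean 0.02). Trat1 rose from 0.153 to 1.25 CPM (2.93), Zap70 by 1.03 and Thy1 from 195 ± 32.3 to 305 ± 42.7 CPM (0.64), and Ctla4 fell from 24.3 ± 12.3 to 4.46 ± 2.16 CPM (−2.45), with adjusted p = 0.0506 with no filter. T cell falls numbered 1 without pMIR replicate 2, pMIR-Sox2 replicate 1 or pMIR-Sox2 replicate 2, and 5 rose with the replicate block. Myeloid markers rose in 3 of 7, fell in 2 and did not pass in 2 (3 and 2 adjusted over the list alone; camera adjusted p = 0.623, fry 0.00854). Itgam rose from 0.558 to 3.79 CPM (2.76), Lyz2 had 2 pMIR counts and a ratio of 22.8 (5.89 to 195), and Cd68 fell (−1.12). Myeloid falls numbered 1 without pMIR replicate 1 or pMIR-Sox2 replicate 1. Summed over each list, T cell markers stood at 308 ± 15.3 CPM in pMIR and 383 ± 38.3 CPM in pMIR-Sox2, and myeloid markers at 49.1 ± 2.46 and 47.9 ± 3.16 CPM. Sums of dendritic cell markers were 516 ± 43.1 and 817 ± 43.2 CPM, of fibroblast markers 203 ± 35.4 and 314 ± 41.2 CPM, of NK cell markers 3.79 ± 0.162 and 8.08 ± 2.33 CPM, and of erythroid and platelet markers 531 ± 80.7 and 405 ± 94.7 CPM. Single genes carry the higher sums, namely Thy1 in the T cell and fibroblast lists, Tcf4 among dendritic cell markers and Klrd1 among NK cell markers. Dendritic cell markers rose in 1 of 9, fell in 4 and did not pass in 4 (1 and 4 adjusted over the list alone; camera adjusted p = 0.41), with Tcf4 rising from 269 ± 34.5 to 656 ± 56.9 CPM (1.29) and Zbtb46 (−1.94) and Flt3 (−1.18) falling; 2 rose with the replicate block. Of 2 NK cell markers 1 rose (1 adjusted over the list alone), Klrd1, with 2 pMIR counts and a ratio of 167 (45.7 to 1383). Erythroid and platelet markers rose in 2 of 4 (2 adjusted over the list alone), Car2 by 1.70 and Hbb-b2 by 1.28, and 1 fell without pMIR-Sox2 replicate 3 or with the replicate block. Fibroblast markers rose in 3 of 5 and 2 did not pass (3 adjusted over the list alone; camera adjusted p = 0.179), namely Col1a1 (2.00), Thy1 and Vcam1 (1.89, adjusted p = 0.0431), and 1 rose with the stricter filter. For Vcam1 the adjusted p was 0.0613, 0.0839 and 0.0796 without pMIR replicates 1, 2 and 3 and 0.22 without pMIR-Sox2 replicate 1.

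The list calls have a limit in the number of libraries, since another split of the 6 libraries into 3 and 3 also gave 13 called lists at the preset correlation, and none other than the real split gave any called gene.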

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

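Of the alternatives in this part, library totals only for the gene lists was chosen after seeing the data. Genes higher and lower numbered 1297 and 584 with a fold minimum of 1.5, which asks for more than a difference from 0. With an estimated correlation 0 lists were called, against 13 with the preset. Fry called 9 lists, 7 of them among the 13. The fry adjusted p was 0.00221 for other Sox genes, and 0.00737 for heavy chain constant regions and for neural progenitor genes. It was 0.00778 for IL-4 and STAT6, 0.0242 for the unfolded protein response, 0.0428 for cholesterol synthesis and 0.0454 for CD40 and NF-kB. With library totals only, 3414 genes rose and 2059 fell, so the balance of rises to falls depends on scaling. Under this and the other alternatives run, apart from the fold minimum, both counts of genes stayed within 1.5 times and Sox2 kept direction and call. Leaving out 1 library gave 2362 to 3321 genes higher, 1783 to 2885 lower, log2 fold changes of 9.35 to 10.47 for Sox2, and 10 to 13 lists. The replicate block gave 3486 genes higher, 3314 lower and 11 lists. It ended the calls of mature B cell identity and neural progenitor genes (0.0632 each). No other call of a list or of a gene taken by the rule changed with it. Of genes named later, Iglc3 (0.0242), Vpreb3 (0.00291) and Lef1 (0.00858) passed with the block, and Enpep (0.0597) lost its call. Of 1738 values of 125 named genes under alternatives, 1689 kept direction and call and 49, over 15 genes, kept direction and missed the threshold, with none reversed. Of 357 list values, 313 kept both, 28 lost the call, 4 gained one and 12 changed sign, of lists that did not pass. These are, as adjusted p, for G2 and M phase 0.851 (library totals only), 0.98 (stricter filter), 0.824 (fry), 0.814 (without pMIR replicate 3) and 0.242 (without pMIR-Sox2 replicate 2), in a range of 0.242 to 0.926 with 1 library left out. They are for T cells 0.969 (library totals only) and 0.839 (without pMIR-Sox2 replicate 3; range 0.785 to 0.934), for WNT targets 0.737 (fry), for glycolysis 0.698 (fry), 0.975 (without pMIR replicate 3) and 0.726 (without pMIR-Sox2 replicate 1; range 0.419 to 0.975), and for histones 0.839 (without pMIR-Sox2 replicate 3; range 0.0362 to 0.839). The cause was not tested. Depth limits folds against genes near 0 in pMIR, where 1 to 3 counts set the ratio. At this number of libraries, 14 of 50 simulated changes of 1.5-fold were found. The simulation changed 200 of 12416 genes, against 43.2% called in these data, so its adjustment was stricter. How often changes below 2-fold were missed here is therefore not known.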

Other observations

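The gene groups of this paragraph and the next, all tests on pMIR-Sox2 replicate 3 and on the mature B cell list, and the test on neural transcripts were chosen only after the results were seen. Immunoglobulin variable, diversity and joining segments fell widely with Sox2, in 135 of 164 tested, and 0 rose in edgeR (0 higher at an unadjusted p under 0.05; 0 with library totals, DESeq2 size factors, the replicate block or any library left out). Falls came from all loci, 56 of 78 in Igh, 77 of 83 in Igk and 2 of 3 in Igl, with a median log2 fold change of −0.96. They numbered 101 to 135 with 1 library left out. Igkc fell from 1077 ± 130 to 524 ± 87.2 CPM (−1.04, adjusted p = 0.000679) and Iglc2 from 166 ± 32.1 to 76.8 ± 25.2 CPM (−1.12). Iglc3 had 215 ± 22.6 and 268 ± 66.1 CPM (adjusted p = 0.16, and 0.0242 with the replicate block). Reads that fit several segments were not counted.

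Genes of early B cell development rose in 7 of 15 tested, fell in 2 and did not pass in 6. With the replicate block 7 rose and 3 fell. Enpep, a rise in the main test, lost its call with the block (0.0597), and Vpreb3 (0.00291, higher) and Lef1 (0.00858, lower) gained one. Igll1, a part of the surrogate light chain, rose from 4 pMIR counts to 3.37 ± 1.49 CPM (adjusted p = 0.000127), and its partners Vpreb1 and Vpreb2, too low to test, had 5 and 1 counts over the pMIR libraries and 47 and 45 over the pMIR-Sox2 libraries. Sox4 and Tcf12 and Cd93 (1.22) were among the rises, and Flt3 (−1.18) and Erg (−1.97) fell. Erg had adjusted p = 0.0803 without pMIR replicate 1, and log2 fold changes of −2.69 without pMIR-Sox2 replicate 1 and −1.48 without pMIR-Sox2 replicate 2. The falls numbered 1 without pMIR replicate 1, 4 without pMIR replicate 2 and 4 without pMIR-Sox2 replicate 3. Rag1 (2 and 3 counts) and Dntt (5 and 7 counts), which act at the same stage, stayed near 0 in both groups. Of 31 cytokine receptor chains, 8 rose, 13 fell and 10 did not pass, and with the replicate block 9 rose and 15 fell. Il2ra fell from 105 ± 28.6 to 22.4 ± 2.51 CPM (−2.23), and Il6ra (−2.48) and Prlr (−3.15) also fell, while Il5ra rose from 217 ± 12 to 725 ± 222 CPM (1.74) and Csf2rb2 by 2.49.

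The number of libraries limits what splits of the samples can show: 10 splits of 3 against 3 are too few for a share under 0.05. For genes, 1 of 10 splits, the real one, gave a count as large (5567 called; the highest other split gave 0). For gene lists, 2 of 10 splits gave a count as large (13 called in the real split and 13 in the highest other). That other split set pMIR replicate 1 and pMIR-Sox2 replicates 1 and 2 against the rest, so it parts 1 pair only, and the replicate block called 11 lists. Among the 4 splits that part all 3 pairs the highest other gave 11 lists, and the 6 others part 1 pair each, so list calls at the preset correlation carry little weight.

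The effect of Sox2 was weaker in pMIR-Sox2 replicate 3. For 169 rising genes its median remaining effect, with 1 as in the other pMIR-Sox2 libraries, was 0.533. Cells without Sox2 among those sorted would alone dilute rises and falls alike, but for 72 falling genes the remaining effect was 0.860, with a lower quartile of 0.760. Rises and falls also differed in pMIR-Sox2 replicate 2 (1.52 and 1.03), so some dilution beside another difference stays open. With all libraries thinned to the depth of this one, the median for rising genes was 0.539, where depth as the source was predicted to bring it near 1. Thinning leaves the CPM unchanged on average, and this library was already at that depth. The median could therefore hardly move, and the test cannot decide on depth. A lower Sox2 level, 0.703 of the mean of the others, stays open, and 3 libraries cannot test it. Sox2 stood at 989, 786 and 624 CPM in replicates 1 to 3. Rising genes, each library set against the others, had effects of 0.977, 1.52 and 0.533. The library with most Sox2 thus did not have the strongest effect.

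Of 36 mature B cell genes 20 were lower with Sox2, though the list's call was lost with an estimated correlation (adjusted p = 0.757), the replicate block (0.0632), fry (0.0541) and without pMIR replicate 2 (0.113) or pMIR-Sox2 replicate 1 (0.0735). A lower share of B cells alone would lower the whole list, but 7 members rose past the threshold beside 20 that fell. Among all 12898 genes 2990 rose, so a lower share beside other changes stays open. With library totals in place of TMM 20 members were still lower, so the choice between these scalings does not account for the falls. The median log2 fold change over all genes was −0.0162 with TMM and 0.0605 with library totals, so this swap could move members little. It cannot decide on a larger error of scaling. Differentiation into plasma cells would raise immunoglobulin, whose share of gene counts was at most 0.547% in pMIR-Sox2 libraries and at least 0.718% in pMIR libraries; this test replaced one on the plasma cell list, which went both ways (8 rose, 11 fell). A change of the B cell state itself may be the source, a hypothesis that was not tested.

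Genes silent in pMIR were read with Sox2. At equal depth 61 genes were gained and 0 lost, where sequencing depth would give similar numbers. Genomic DNA or unspliced RNA would raise silent genes in general, but 91.7% of 6729 silent protein-coding genes stayed at or under 3 counts, although the share of entries in no feature was higher with Sox2 in all 3 pairs (12.2% and 14.6%, 13.1% and 13.4%, 11.4% and 12.1%), so a smaller part from either source stays open. Neural cells would bring their abundant transcripts, whose median over 19 of 20 listed genes was at most 0.0919 CPM, with Snap25, Stmn2 and Dcx at 0 in both groups, while Mbp (63.7 and 55.0 CPM) was read, and the sort on mCherry would remove uninfected cells. Activation of such genes by Sox2 may be the source, a hypothesis that was not tested.

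The pMIR libraries held traces of transcripts that are abundant with Sox2, such as 8, 2 and 12 counts of Pcp4 and 2, 1 and 7 of Apod in replicates 1 to 3, beside 20, 7 and 37 of Sox2. Their source was not tested, so folds of such genes over pMIR are relative to these traces.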
